A study of Ovis aries with 12 samples.

How the data were processed

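Small RNA was measured by sequencing in cultured pulmonary artery endothelial cells from lambs. Per the labels' protocols, persistent pulmonary hypertension of the newborn (PPHN) was modelled by tying off the ductus arteriosus before birth, at about 125 days of gestation, and the vessel stayed closed for 5 to 7 days. Control lambs had sham surgery. Cells were taken from the main pulmonary artery with collagenase, purified with magnetic beads carrying a CD31 antibody, and grown between passages 2 and 5. Libraries were made from total RNA with a TruSeq small RNA kit, per the labels' protocols. The 12 libraries comprise 6 controls, numbered 1 to 6, and 6 PPHN libraries, numbered 7 to 12. The numbers are not shared between groups and pair no samples. The labels do not say whether each library came from its own lamb, so p-values measure the spread between these libraries, part of which may be technical.

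The authors deposited raw read counts per miRNA entry for each library, per the file headers. Trim Galore 0.2.5 and Bowtie 1.1.1 are named by the submitters' processing notes, and their roles and settings are not given in the sources used here, nor are a genome build or the miRNA reference. The counts of 470 entries are whole numbers, and each entry has at least 143 counts over the 12 libraries. Entries carry miRBase names from many species: 149 of them join several names, 92 have a sheep name (prefix oar), and the others have names of cow (bta), human (hsa) or other species. Reads can therefore be counted in more than 1 near-identical entry. The total over these 470 entries is not the sequencing depth of a library, because other reads are not used here. The authors also deposited p-values and q-values per entry from DESeq, DESeq2 and edgeR, and a log2 fold change from each tool. The file headers name the tool of each of these columns except 1 of q-values, which was read as that of DESeq2 because it stands after the DESeq2 p-values. The tools' versions are not given in the sources used here.

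From the counts, differences between PPHN and control were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test with robust fitting) after filterByExpr, which kept 468 entries, and TMM scaling over these entries. Adjusted p-values are Benjamini-Hochberg values over all tested entries unless stated otherwise, with a threshold of 0.05. The standard error (SE) of a log2 fold change was taken from the size of the fold change and its F statistic. Levels are CPM, the counts of an entry scaled to a common total of the listed entries per library, after TMM scaling, and log2 CPM values used a prior count of 2. The common biological coefficient of variation was 0.730. Library totals and the share of counts in the 10 most abundant entries were compared with exact two-sided permutation tests over all 924 assignments of 6 against 6. Libraries were checked for duplicates with a chi-square test of each pair of libraries, and the lowest chi-square per degree of freedom was 418, far above sampling noise. Exact (Clopper-Pearson) 95% intervals were computed for single CPM values; they and the floors of 3 counts, which lie between 0.169 and 1.33 CPM before scaling, cover counting error only.

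Before the data were examined, 19 miRNA lists were fixed from general knowledge of endothelial cells, other vessel and lung cell types, pulmonary hypertension and miRNA families. An entry belongs to a list if 1 of its names, without species prefix, arm and copy number, equals a member. The 16 lists with at least 3 tested entries were tested with camera (limma 3.58.1, preset inter-gene correlation 0.01), with Benjamini-Hochberg adjustment over the 16 lists. Camera with an estimated correlation and fry were run beside it. The gene table of the sheep assembly ARS-UI_Ramb_v3.0 was used only to see which genes neighbour each other: all 38 hairpins behind the sheep-named entries of the DLK1-DIO3 list were found in it.

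Named entries follow a rule fixed before the data were examined. It takes the 5 entries with the lowest p in each direction and a mean of at least 10 CPM in 1 group, when fewer than 5 pass the threshold, and the 5 most abundant entries. It also takes up to 4 entries with the lowest p from each list, and always miR-126, miR-21, miR-210, miR-17, miR-92a, miR-204, miR-145 and miR-143. Entries named beyond the rule are said to be chosen after their values were seen.

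The alternatives fixed before the data were examined were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no filter, a filter of at least 10 CPM in at least 6 libraries, the list tests above, lists with the more abundant arm only, other numbers of abundant entries, and leaving out each library in turn. Leaving out 3 libraries with little miR-126, leaving out 9 entries that nearly duplicate others, and adding the miR-126 level as a covariate were chosen after seeing the data.

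The tests were tested on simulated data: in 10 simulations of the 6 against 6 comparison with 200 changed entries, an average of 445.8 entries were tested. The edgeR test recovered 26.1% of the 2-fold and 71.7% of the 4-fold changes, and 1.33% of its calls were false. DESeq2 recovered 42.3% and 82.0% with 3.88% false calls. Camera called a list of 12 raised entries in 10 of 10 simulations and a list of 12 unchanged entries in 0 of 10. These rates may not hold for the real libraries. There, 51 of 100 drawn splits gave at least the 3 camera lists of the real split, and the highest other DESeq2 count was 55 entries. The fibroblast and miR-17-92 lists had estimated correlations of 0.449 and 0.292, against the preset 0.01.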

Results

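The study asked which miRNAs differ between pulmonary artery endothelial cells of lambs with PPHN and of control lambs. Counts of 470 miRNA entries were analysed in 6 control and 6 PPHN libraries. The counts over all entries ranged from 2250077 in PPHN 11 to 17740932 in PPHN 7. They averaged 6.87e+06 ± 2.74e+06 in control and 7.16e+06 ± 5.93e+06 in PPHN (SD, n = 6 each; exact two-sided permutation p = 0.907).

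The most abundant entry in both groups was oar-miR-21, a miRNA known for high levels in dividing and stressed cells, at 173559 ± 34301 CPM in control and 220369 ± 67642 CPM in PPHN (SD, n = 6). The other 4 of the 5 entries with the highest mean over all libraries were oar-miR-143, a miRNA of contractile vessel cells (132658 ± 147031 CPM in control, 92004 ± 104001 CPM in PPHN), oar-miR-22-3p (81563 ± 23946 and 98581 ± 7915 CPM), bta-miR-3600 and oar-let-7f. The entries oar-miR-22-3p and bta-miR-3600 had nearly the same counts in every library, with a ratio of total counts of 0.994. The 10 most abundant entries held 71.3 ± 5.05% of the counts in control and 68.7 ± 8.28% in PPHN (SD, n = 6; exact two-sided permutation p = 0.517). The share of oar-miR-21 alone was 17.7 ± 2.59% in control and 20.9 ± 3.98% in PPHN (exact two-sided permutation p = 0.132).

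In PPHN cells, oar-miR-26b was 1.44-fold lower than in control cells, at 1917 ± 111 CPM against 2768 ± 300.1 CPM (SD, n = 6), and every PPHN library lay below every control library. The entries oar-miR-30b, a member of the miR-30 family found in endothelial cells, and bta-miR-342 were 1.40-fold and 1.44-fold lower with the same separation of the groups. On the other side, hsa-miR-125a-5p, an abundant miRNA of the miR-125 family, was 1.64-fold higher in PPHN, at 6596 ± 1339 CPM against 4028 ± 946 CPM, and hsa-miR-34c-5p, of the p53-induced miR-34 family, was 3.50-fold higher, at 65.7 ± 44.6 CPM against 18.7 ± 8.67 CPM. None of these differences passed the threshold of the edgeR test after adjustment.

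With edgeR, 0 of 468 tested entries passed a Benjamini-Hochberg adjusted p of 0.05, and the lowest adjusted p was 0.190. At an unadjusted p under 0.05 there were 49 entries, 23 higher and 26 lower in PPHN, where 23.4 would be expected by chance alone; DESeq2 had 72 and limma-voom 44. The balance moved with the processing, to 20 higher and 33 lower with upper-quartile scaling and 32 higher and 14 lower with the filter of 10 CPM. Without PPHN 11 there were 32. The lowest p on the lower side belonged to bmo-miR-2779, an entry with a silkworm name (log2 fold change -1.57, SE 0.36), oar-miR-26b (-0.53, SE 0.12), ssc-miR-331-5p (-1.05, SE 0.25), oar-miR-30b (-0.49, SE 0.14) and bta-miR-342 (-0.52, SE 0.17). On the higher side they were cgr-miR-874 (log2 fold change 1.21, SE 0.30), hsa-miR-125a-5p (0.71, SE 0.19), gga-miR-1692 (1.87, SE 0.55), hsa-miR-34c-5p (1.81, SE 0.54) and ssc-miR-1285 (1.62, SE 0.53). Without PPHN 8, bmo-miR-2779 passed the threshold, with a log2 fold change of -1.90 (adjusted p = 0.0321, edgeR with Benjamini-Hochberg adjustment; up to 0.433 with another library left out).

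The groups did not overlap for 6 entries, where 1.01 would be expected by chance (0.216% of assignments for 1 entry). They were oar-miR-26b, oar-miR-30b and bta-miR-342, all lower in PPHN, and cgr-miR-874, bta-miR-2387 and bta-miR-361, all higher. The last pair was chosen after its values were seen: bta-miR-2387 was near the floor, at 0.993 ± 0.566 CPM in control and 3.05 ± 0.964 CPM in PPHN, and bta-miR-361 was at 132 ± 32.0 CPM and 196 ± 24.0 CPM (SD, n = 6). The entry cgr-miR-874 had only 16 to 93 counts per control library and 37 to 127 per PPHN library, so counting error bears on its separation. The higher levels of gga-miR-1692 and ssc-miR-1285 came from PPHN 8, PPHN 11 and PPHN 12. In those libraries gga-miR-1692 stood at 257, 281 and 188 CPM, against 30.4 to 50.4 CPM in the other 9. The level of hsa-miR-34c-5p was highest in PPHN 11 and PPHN 8. Without control 2, PPHN 8 and PPHN 11 together, the log2 fold change was 1.03 for hsa-miR-34c-5p, 1.02 for gga-miR-1692 and 0.80 for ssc-miR-1285.

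**Figure D1:**
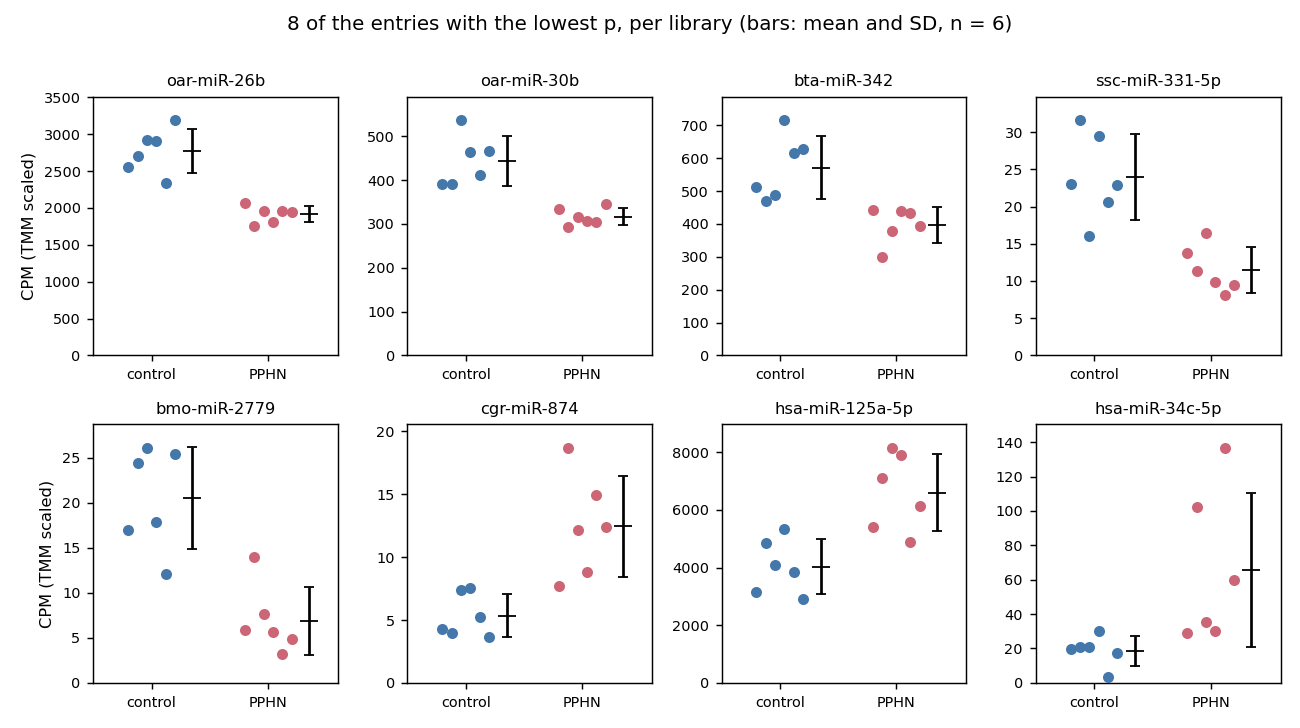
CPM after TMM scaling (linear axis from 0) of 8 of the entries with the lowest p in the 6 control (blue) and 6 PPHN (red) libraries, 1 point per library, with the mean and SD beside them. The groups do not overlap for oar-miR-26b, oar-miR-30b, bta-miR-342 and cgr-miR-874, and hsa-miR-34c-5p is highest in PPHN 11 (137 CPM) and PPHN 8 (102 CPM).

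DESeq2 called 12 entries at a Benjamini-Hochberg adjusted p under 0.05, against 0 by edgeR and 0 by limma-voom on the same counts. The 5 lower in PPHN were oar-miR-26b (log2 fold change -0.51, DESeq2 adjusted p = 4.7e-06), oar-miR-30b, bmo-miR-2779, ssc-miR-331-5p and bta-miR-342. The 7 higher in PPHN were cgr-miR-874, hsa-miR-125a-5p, bta-miR-2387, gga-miR-1692, hsa-miR-34c-5p, bta-miR-361 and bta-miR-2340, of which bta-miR-2340 was chosen after its values were seen. The authors' deposited table also holds 12 entries with an adjusted p under 0.05, 7 higher and 5 lower, in a column that names no tool and was read as DESeq2's from its place, with an adjusted p of 6.04e-06 for oar-miR-26b. By the authors' own edgeR values 0 entries passed (lowest adjusted p = 0.192, 55 at an unadjusted p under 0.05) and by their DESeq values 0 passed (lowest adjusted p = 1, 0 at an unadjusted p under 0.05).

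The miRNAs of the miR-17-92 cluster and its paralogs, which promote proliferation and vessel growth, were lower in PPHN for 14 of 15 tested entries, with a median log2 fold change of -0.31. Several of these entries are miR-92a under names of different species, so the 15 are not separate miRNAs (estimated inter-gene correlation 0.292). The most abundant, bta-miR-92a, was 1.44-fold lower at 36879 ± 6498 CPM against 53207 ± 12576 CPM (SD, n = 6), oar-miR-25 was 1.45-fold lower, and oar-miR-17-5p was 1.26-fold lower. As a list they fell (camera adjusted p = 0.0187; adjusted p = 0.634 with an estimated correlation), while 0 entries passed singly, and 0 adjusted over the list alone. Without PPHN 12 the list had a camera adjusted p of 0.0552, and with the more abundant arm only it had 0.125.

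The fibroblast markers, which belong to another cell type of the vessel wall, were lower in PPHN for 12 of 12 entries, with a median log2 fold change of -0.69. The 12 entries stand for only 5 named members (estimated inter-gene correlation 0.449). Most of the entries are miR-199 or miR-214 entries, so they are not separate markers. Among them dre-miR-140-3p was at 305 ± 50.6 CPM in PPHN against 562 ± 256 CPM in control, bta-miR-3604, whose entry also carries a miR-199b name, at 2324 ± 1743 against 4200 ± 3094 CPM, and bta-miR-199b at 12.6 ± 18.3 against 80.7 ± 130 CPM (SD, n = 6). The control mean of bta-miR-199b rests on control 1 (1445 counts) and control 3 (1059 counts), against 0 to 25 counts in the other controls. Its log2 fold change turned to 1.38 with limma-voom. The list fell (camera adjusted p = 0.0350; adjusted p = 0.634 with an estimated correlation), with 0 entries past the threshold adjusted over the list alone. The camera adjusted p was 0.199 without control 3, 0.0655 without PPHN 8 and 0.137 without PPHN 11, and 0.740 without the 3 libraries with little miR-126.

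The endothelial list rose (camera adjusted p = 0.0486; adjusted p = 0.634 with an estimated correlation), with 15 of 23 entries higher, a median log2 fold change of 0.10 and 0 entries past the threshold adjusted over the list alone. Its lowest p values include oar-miR-10b, a Hox-cluster miRNA, at 294 ± 383 CPM in PPHN against 43.1 ± 70.9 CPM in control, bfl-miR-125b at 3873 ± 815 against 2641 ± 1097 CPM, and oar-miR-99a at 2176 ± 690 against 1432 ± 538 CPM (SD, n = 6). The level of oar-miR-10b reached 937 CPM in PPHN 8 and 588 CPM in PPHN 11, and the other 10 libraries lay between 3.14 and 186 CPM. The list's camera adjusted p was 0.128 without control 4, 0.203 without control 5, 0.0655 without PPHN 8 and 0.0694 without PPHN 11, and 0.0663 without near-duplicate entries, of which the list holds oar-miR-125b and bfl-miR-125b. The endothelial miRNA miR-126 had no direction that stood out from the spread: log2 fold changes were -0.24 (SE 1.30) for ccr-miR-126-3p, -0.52 (SE 1.27) for bta-miR-126-5p and 0.16 (SE 1.104) for gga-miR-126-3p.

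The list of the miR-15, miR-16 and miR-424 family had 8 of 9 entries lower, with oar-miR-16b 1.44-fold lower at 4464 ± 867 CPM against 6432 ± 1207 CPM (SD, n = 6) and a camera adjusted p of 0.0503 (adjusted p = 0.634 with an estimated correlation). It lay under the threshold without control 2 (adjusted p = 0.0388), control 4 (0.0462), control 6 (0.0410), PPHN 7 (0.0124), PPHN 9 (0.0169), PPHN 10 (0.0314) or PPHN 12 (0.0261), and with RLE scaling (0.0491). It lay above it without control 1, control 3, control 5, PPHN 8 or PPHN 11, with an adjusted p of up to 0.262. The mean log2 CPM of the list was 3.44 in PPHN 8 and 3.52 in PPHN 11, and the lowest control was control 4 at 4.95. The other PPHN libraries lay within the range of the controls, so the lower mean level of the list rested on PPHN 8 and PPHN 11. All 4 miR-181 entries were lower, among them bta-miR-181b at 677 ± 234 CPM against 1090 ± 354 CPM, with a camera adjusted p of 0.117, 0.0124 without control 2 and 0.0264 without control 2, PPHN 8 and PPHN 11 together (adjusted p = 0.634 with all libraries and an estimated correlation).

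The hypoxia list had 7 entries higher and 8 lower (camera adjusted p = 0.425), and bta-miR-210, the standard miRNA of the hypoxia response, was at 60.5 ± 76.3 CPM in PPHN and 41.2 ± 48.8 CPM in control (SD, n = 6). In this list oar-miR-26a was 1.33-fold higher while oar-miR-26b was lower, and oar-miR-103 was 1.41-fold lower. The pulmonary hypertension list had 23 entries higher and 18 lower (camera adjusted p = 0.425). Its member bta-miR-204 was at 1945 ± 1269 CPM in PPHN and 1058 ± 629 CPM in control. Of the flow-responsive list 10 entries were higher and 13 lower (camera adjusted p = 0.993). Adjusted over the list alone, 1 entry passed the edgeR threshold in the hypoxia list (oar-miR-26b) and 0 in the pulmonary hypertension and flow-responsive lists.

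The p53 and senescence list had 8 of 10 entries higher (camera adjusted p = 0.378; adjusted p = 0.634 with an estimated correlation; camera adjusted p = 0.0264 without control 2, PPHN 8 and PPHN 11 together), among them bta-miR-192 at 106 ± 30.8 CPM in PPHN against 68.8 ± 12.3 CPM in control (SD, n = 6). In the inflammation list 5 of 7 entries were higher (camera adjusted p = 0.446), but ipu-miR-155, a miRNA of inflammatory activation, was 1.79-fold lower and hsa-miR-9-5p was 1.77-fold lower. The median log2 fold change of the inflammation list turned from 0.34 to -0.37 without control 2, PPHN 8 and PPHN 11 together. The list of miRNAs that target endothelial nitric oxide synthase had 10 of 15 entries higher (camera adjusted p = 0.370). Its median log2 fold change of 0.10 turned to -0.21 without control 2, PPHN 8 and PPHN 11 together. The let-7 list had 8 of 12 entries higher with a median log2 fold change of 0.03 (camera adjusted p = 0.446), which turned to -0.03 with upper-quartile scaling, and oar-let-7a was 1.08-fold higher. The miR-30 list had a median of -0.02 but a mean of 0.05 (camera adjusted p = 0.993), and its median was 0.01 with RLE scaling. The list of miR-130 and miR-301 had 5 of 7 entries lower (camera adjusted p = 0.976). Adjusted over the list alone, 1 entry passed in the miR-30 list (oar-miR-30b) and 1 in the inflammation list (hsa-miR-125a-5p), and 0 in the others of this paragraph and in the miR-181 list and that of the miR-15, miR-16 and miR-424 family.

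**Figure D2:**
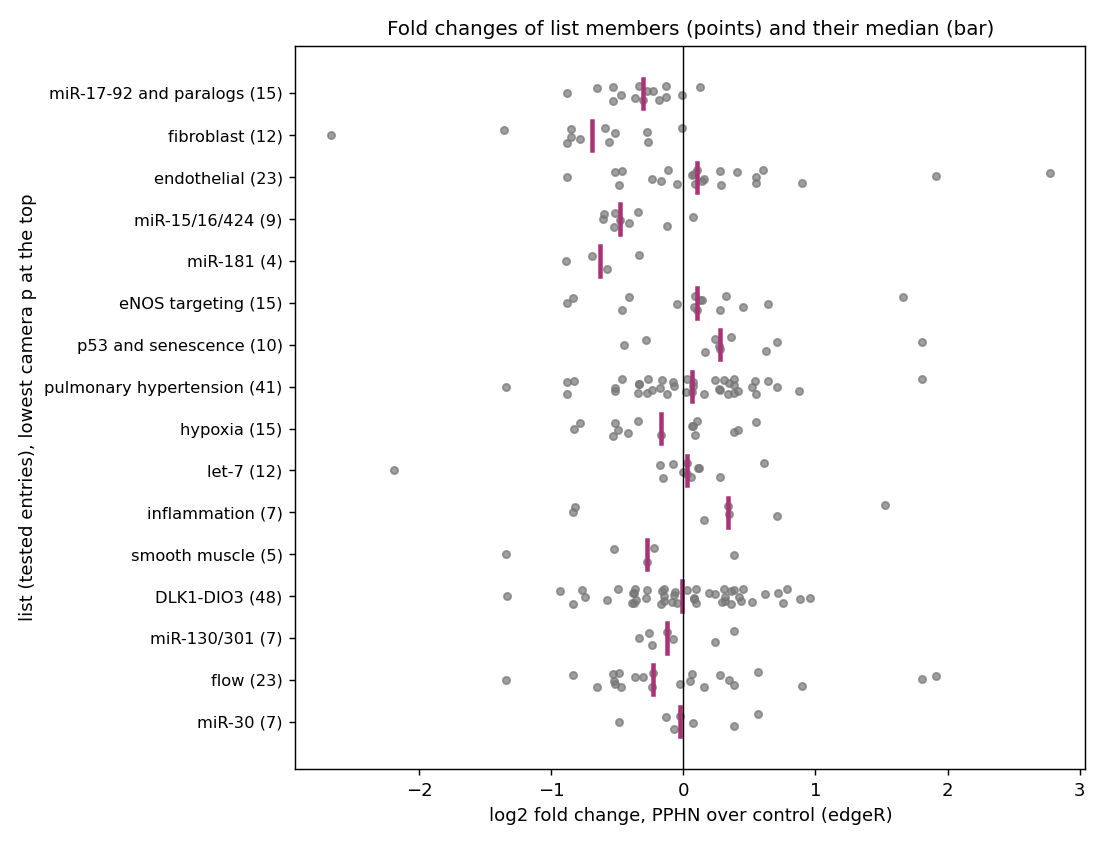
Log2 fold changes of PPHN over control (edgeR) for the tested entries (grey points) of the 16 lists, with the median of each list as a bar and the number of entries in parentheses. All 12 fibroblast entries and 14 of the 15 entries of the miR-17-92 list lie below 0, and the 48 entries of the DLK1-DIO3 list lie on both sides.

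Markers of other cell types differed widely between libraries of the same group. The smooth muscle list had 4 of 5 entries lower in PPHN (camera adjusted p = 0.575, 0 past the threshold over the list alone). Its member oar-miR-143 stood between 104433 and 301222 CPM in control 1, control 3, control 6, PPHN 7, PPHN 9 and PPHN 12, and between 2157 and 18366 CPM in the other 6 libraries. The level of ssc-miR-145-5p, from the same cluster, followed, at 47.8 to 223 CPM in the first and 1.00 to 5.65 CPM in the second of these sets. The entry bta-miR-486, a red blood cell miRNA, was at 70.6 ± 64.5 CPM in PPHN and 317 ± 314 CPM in control (log2 fold change -2.16, SE 0.73). The blood list holds only 2 tested entries, both lower, and too few for a set test, of which 1 passed adjusted over the list alone. The epithelial list also holds 2 entries, both higher and 0 past the threshold: oar-miR-200b was at 398 CPM in control 4, at 0 to 4.74 CPM in the other 5 controls, and between 29.5 and 150 CPM in the PPHN libraries. Both entries of the miR-29 list were higher, with 0 past the threshold.

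The miR-126 level split the libraries within both groups. The abundant entry mmu-miR-126b-3p, chosen after its values were seen, stood at 161 CPM in control 2, 195 CPM in PPHN 8 and 176 CPM in PPHN 11, against 10588 to 98168 CPM in the other 9 libraries. In control 2 it had 816 of 4101316 counts, or 199 CPM before scaling (exact 95% interval 186 to 213). The entry bta-miR-126-5p was at 4.67 to 7.30 CPM in the same 3 libraries and at 181 to 2442 CPM in the others. The entries of the DLK1-DIO3 cluster, an imprinted chromosome region, moved together across libraries (estimated inter-gene correlation 0.914) but not between the groups, with 24 entries higher and 24 lower (camera adjusted p = 0.582) and 0 past the threshold adjusted over the list alone. Its member oar-miR-494-3p was at 13.1 ± 12.1 CPM in PPHN and 32.9 ± 25.9 CPM in control (SD, n = 6). The entry oar-miR-127 of this cluster, chosen after its values were seen, ranged from 128 CPM in PPHN 8 to 7536 CPM in PPHN 11. The first principal component of log2 CPM, led by mmu-miR-126b-3p, held 41.1% of the variance and averaged 3.33 ± 17.1 in PPHN and -3.33 ± 17.9 in control (exact two-sided permutation p = 0.519).

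**Figure D3:**
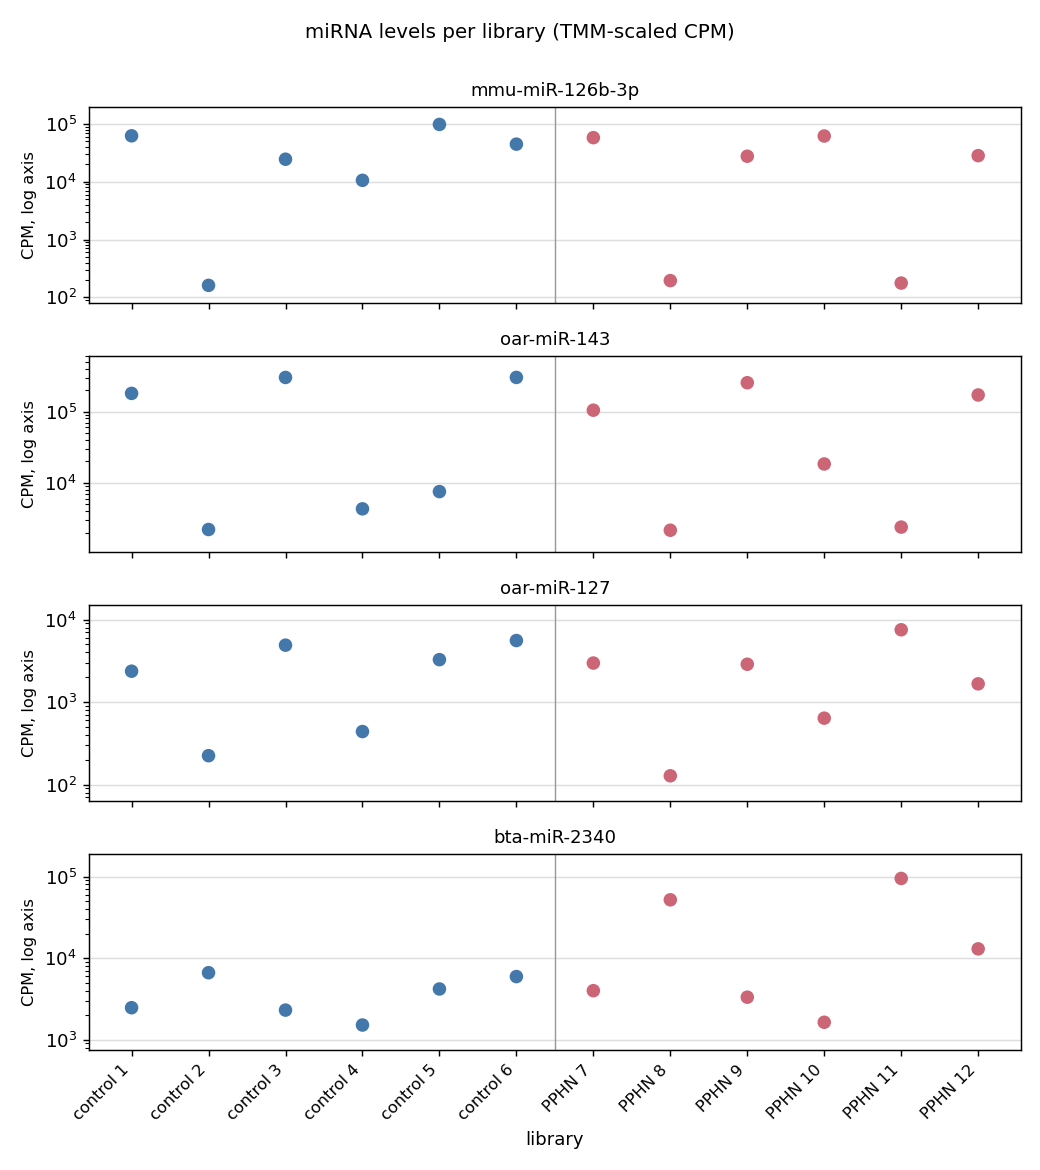
CPM after TMM scaling (log axes) of 4 entries in each of the 12 libraries, 1 point per library, with control in blue and PPHN in red. The entry mmu-miR-126b-3p lies under 200 CPM in control 2, PPHN 8 and PPHN 11, oar-miR-143 and oar-miR-127 differ by more than 10-fold within each group, and bta-miR-2340 is highest in PPHN 11 (94769 CPM) and PPHN 8 (51855 CPM).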

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

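Every test of an explanation below, except the counts of other splits for ductal ligation, DESeq2 and camera, was chosen only after the result was seen. In 8 of 96 groups of 6 libraries, 1 library stood farther from the others than Dixon's test allows; chance would give about 5% of groups. In control 2, mmu-miR-126b-3p was at 161 CPM against 10588 to 98168 CPM in the other controls, and ccr-miR-126-3p was at 3.36 CPM against 182 to 1799 CPM. In control 5, hsa-miR-34c-5p was at 3.33 CPM against 17.7 to 30.0 CPM. In control 3, oar-miR-25 was at 24.7 CPM against 33.4 to 37.7 CPM and oar-miR-17-5p at 371 CPM against 622 to 843 CPM. In control 1, bta-miR-192 was at 45.6 CPM against 63.9 to 76.7 CPM. In PPHN 7, oar-miR-22-3p was at 83385 CPM against 98223 to 105313 CPM, and bta-miR-3600, whose counts follow it, at 82851 CPM against 97625 to 104704 CPM.

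Control 2, PPHN 8 and PPHN 11 held little miR-126, and other cell types are candidate sources. These libraries also had the lowest totals, at 4101316, 2655849 and 2250077 counts, against 4697471 or more in the others. Whether the low totals bear on miR-126 was not tested. The median difference of the endothelial list from the median of the 12 libraries was 0.31, 0.50 and 0.30 log2 units, against -0.00749, -0.0171 and -0.0256 over all 468 entries with the same scaling (not tested). This median cannot decide whether the cells are endothelial, since bta-miR-126-5p of the same list differed by -6.65, -7.26 and -6.65. Smooth muscle cells would bring miR-143. In all 3 libraries oar-miR-143 lay at least 4.20 log2 units below the median of the 12 libraries (highest difference -4.20). This argues only against smooth muscle cells rich in miR-143. That median lies between a high and a low set of libraries. The low set also includes control 4, control 5 and PPHN 10, which held much miR-126. Of the smooth muscle list, 3 of the 5 tested entries also stand in another list, and 4 have a mean of at least 10 CPM here. Of the 12 entries of the fibroblast list, 3 stand in another list and 9 have a mean of at least 10 CPM. The list lay below the median by 1.58 (difference -1.58) or more in PPHN 8 and PPHN 11. Most of its entries are miR-199 or miR-214 entries, so this argues only against fibroblasts rich in these miRNAs there. In control 2 the difference was 0.0550, which leaves fibroblasts open. No explanation beyond these cell types was tested: control 2 came from sham surgery, and ductal ligation in PPHN 8 and PPHN 11, loss of miR-126 in culture, another cell type that passed the CD31 beads and a mislabelled sample stay open.

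The mean log2 CPM of the entries higher in PPHN at an unadjusted p under 0.05 was highest in PPHN 8, PPHN 11 and PPHN 12. Single entries differed: among the PPHN libraries, hsa-miR-125a-5p was lowest in PPHN 11 and bta-miR-192 was lowest in PPHN 12. PPHN 8, PPHN 11 and PPHN 12 also held much hhi-miR-7641, a name given to ribosomal RNA fragments (7895, 8650 and 7331 CPM). If fragments of other RNAs were the cause, the mean of the entries higher in PPHN should follow that of 13 fragment entries within both groups. The mean was taken over 22 of the 23, without hsa-miR-7641, itself a fragment entry. The list of fragment entries was written after the counts were seen. Within the PPHN libraries Pearson's r was 0.83 (exact permutation p = 0.0528, adjusted p = 0.106 over the 2 groups) and Spearman's rho 0.886 (exact permutation p = 0.0333, adjusted p = 0.0667), and r was 0.79 without the 2 libraries farthest from the median. Within the controls r was 0.0471 (exact permutation p = 0.939, adjusted p = 0.939), rho 0.143 (exact permutation p = 0.803, adjusted p = 0.803) and r 0.186 without the 2 farthest libraries, and control 6 had the highest fragment level (7.62) with the 22 entries at 5.41. The fragment entries averaged 6.36 ± 0.72 in control and 6.52 ± 0.66 in PPHN (SD, n = 6, exact two-sided permutation p = 0.686). This decides nothing because the entries go both ways (log2 fold change 1.84 for hsa-miR-7641 and -1.62 for mmu-miR-6240), and fragments stay open. For ductal ligation, 5 of 100 drawn splits of the libraries gave at least the 49 entries of the real one (highest other 96). The share was 5%, with a binomial 95% interval of 1.64% to 11.3% for the draw of 100 of the 462 splits. The interval is approximate, because the real split was always included and the others were drawn without replacement. The rule written beforehand took a share of 5% or more as against ligation, but the interval reaches to both sides of 5%. Ligation and chance therefore cannot be told apart with the splits drawn.

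Several entries kept 1 ratio of counts in all libraries: 9 of 60378 pairs had a log2 ratio with an SD under 0.05. These pairs were picked for a small spread, so a lower-tail chi-square test of each was adjusted with Bonferroni over all 60378 pairs, and 0 pairs passed. The lowest adjusted p was 0.197, for oar-miR-22-3p with bta-miR-3600 (chi-square per degree of freedom 0.0536). The less counted entries of the 9 pairs held 11.2% of all counts. Whether the same reads were counted for both entries of a pair, or the entries are expressed together, stays open.

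Chance could not be excluded for the counts of calls by DESeq2 and camera, tested on 100 of the 462 ways to split the 12 libraries into 2 sets of 6, the real one included. With edgeR the real split gave 0 entries, so all 100 splits had to give as many (highest other 1), and this says nothing on chance. With DESeq2 the real split gave 12 entries and 5 of the 100 splits gave as many, the highest other giving 55. With camera the real split gave 3 lists and 51 of the 100 gave as many (highest other 8). A split that parts control 1, control 2, control 4, PPHN 8, PPHN 10 and PPHN 12 from the others gave the 55 DESeq2 entries, and one that parts control 1, control 3, control 5, control 6, PPHN 7 and PPHN 10 from the others gave 42. Both splits gave 0 edgeR entries past the threshold, but 94 and 96 at an unadjusted p under 0.05, against 49 in the real split. They are the drawn splits with the most DESeq2 entries, and no structure of the libraries was tested.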

How the results depend on the processing

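Variants for normalized values do not apply, since the file holds counts. No paired analysis was possible because the groups share no replicate numbers. The 3 alternatives that use the miR-126 level or leave out near-duplicate entries were chosen after seeing the data. Of 46 named entries 38 kept the sign of their fold change in all alternatives run, and of 16 lists 9 kept that of their median; the reversals below concern values that passed no threshold. The cause of the changes was not tested unless stated.

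The count of entries past the threshold was 0 with edgeR, RLE or upper-quartile scaling, limma-voom, either filter and all 3 later alternatives, and 12 with DESeq2; leaving out 1 library gave 0 to 1. At an unadjusted p under 0.05 leaving out 1 library gave 32 to 59 entries, and there were 27 without control 2, PPHN 8 and PPHN 11, with fewer libraries tested. The 3 lists called by camera became 0 with an estimated correlation, 0 with fry, 0 with the more abundant arm only, 1 with the miR-126 covariate, 2 without near-duplicate entries (endothelial adjusted p = 0.0663), 5 without the 3 libraries (now with DLK1-DIO3, adjusted p = 0.00847, and miR-181 and p53 with senescence, both 0.0264), and 1 to 6 with 1 library left out. The difference in library totals, PPHN minus control, ran from -1.83e+06 to 1.27e+06 counts with 1 library left out (lowest exact permutation p = 0.348). The difference in the share of the 10 most abundant entries, -2.58 percentage points, was 3.17 for the most abundant entry alone (exact permutation p = 0.132), 0.428 for 25 entries and 1.77 without the 3 libraries. With 1 library left out it ran from -4.44 (without PPHN 9) to -0.253 (without PPHN 11), with a lowest exact permutation p of 0.275.

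Log2 fold changes that turned were -0.0274 for oar-let-7f with upper-quartile scaling, 0.29 for oar-miR-143 and 1.38 for bta-miR-199b with limma-voom, and 0.0251 for oar-miR-127 with the 10 CPM filter. Without the 3 libraries they were 0.0455 for ccr-miR-126-3p, -0.64 for bta-miR-210 and -0.80 for oar-miR-200b, and list medians were 0.15 for miR-130 with miR-301, -0.37 for inflammation and -0.21 for nitric oxide synthase. With the miR-126 covariate they were 0.16 for ccr-miR-126-3p, -0.0629 for bta-miR-210, -0.21 for oar-miR-200b and 5.44e-05 for mmu-miR-126b-3p, the covariate itself, and list medians 0.0446 for DLK1-DIO3 and -0.0527 for nitric oxide synthase. The DLK1-DIO3 median was 0.00759 with RLE scaling and 0.0528 with the more abundant arm, miR-30 was 0.0141 with RLE scaling, the pulmonary hypertension median was -0.000997 with the more abundant arm, and let-7 was -0.00183 without near-duplicates.

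With 1 library left out, log2 fold changes ran from -0.0714 to 0.0901 for oar-let-7f, -0.73 to 0.29 for ccr-miR-126-3p, -0.95 to 0.0405 for mmu-miR-126b-3p, -0.44 to 1.24 for bta-miR-210, -0.21 to 6.16 for oar-miR-200b (6.16 without control 4) and -0.76 to 0.23 for oar-miR-127. List medians ran from -0.16 to 0.0736 for pulmonary hypertension, -0.72 to 0.27 for DLK1-DIO3, -0.0370 to 0.0937 for let-7, -0.17 to 0.22 for miR-30, -0.33 to 0.00477 for miR-130 with miR-301 and -0.17 to 0.32 for nitric oxide synthase. Depth limits the entries near the floor, such as bta-miR-2387.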

Other observations

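Values in this part were picked from the tables after the data were seen, while the list and the leaving out of each library were fixed before. The imprinted DLK1-DIO3 cluster set some cultures apart: its 48 entries averaged 0.19 log2 CPM in PPHN 8, 1.20 in control 2, 1.505 in control 4 and 2.12 in PPHN 10, against 2.89 to 5.55 in the other 8 libraries, with the highest value in PPHN 11. So PPHN 8 and PPHN 11, alike in miR-126, lay at opposite ends for this cluster. The camera adjusted p of this list was 0.0127 without control 2, 0.0457 without control 4 and 0.00584 without PPHN 11, each with lower levels in PPHN, 0.582 with all 12 libraries, and between 0.00584 and 0.996 over all alternatives. These values rest on a preset correlation of 0.01, while the estimated correlation of the list is 0.914 and gives an adjusted p of 0.996 with all 12 libraries.

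The miR-199a and miR-214 entries, which come from 1 host transcript, were nearly missing from PPHN 11: oar-miR-199a-3p was at 55.4 CPM and bta-miR-214, chosen after its values were seen, at 0 counts, against 687 to 8334 CPM and 8.35 to 336 CPM in the other 11 libraries. The floor of 3 counts in PPHN 11 is 1.33 CPM before scaling. The libraries PPHN 7 and PPHN 9 had the highest rank correlation of all pairs within PPHN, with a Spearman rho of 0.967 across entries, which are not independent replicates, where the median pair within PPHN had 0.875. The entry cfa-miR-31, an endothelial list member, was at 2.67 CPM in control 5 and 27.7 CPM in control 6, and between 94.1 and 837 CPM in the other 10 libraries.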
